A study of Homo sapiens with 6 samples.

How the data were processed

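RNA was measured by short-read sequencing in 6 samples of MCF-7, an oestrogen receptor positive breast cancer cell line: 3 labelled wild type and 3 labelled LATS1/2 knockout. Per the labels' protocols, RNA was isolated with Trizol from cells at passage 12 to 18, and libraries were made from 1 µg of total RNA with an Illumina TruSeq kit. The submitters' processing notes name Bowtie 0.12.2 and the genome builds hg38 and mm8, with no role for any of them. The program that turned alignments into expression values and the gene annotation release are not given in the sources used here.

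The authors deposited 1 table per sample with an Ensembl gene ID, a gene symbol and 1 value for each of 60725 genes. The deposited values were taken as TPM (the share of transcripts, scaled to 1000000 per library) because each table sums to 1000000, although the file headers call the column PFKM. TPM keeps no record of how many reads were sequenced, so the depth of each library is unknown and no counting error can be given. A TPM is a share of the library: a rise of a few abundant genes lowers the values of all others, and a loss of long transcripts raises the values of short ones. The design fixed before the data were examined assumed raw read counts with a count-based test, and named the test used here in case the files held normalized values only.

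Samples were grouped by the genotype in their labels. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicate numbers were not used as a block in the main test. Expression was compared on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and robust estimation of the spread, for the 16198 genes with a mean of at least 1 TPM over all 6 samples. A fold change on this scale understates the change of genes with few TPM. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Reported errors are the SD of the TPM over 3 samples and the standard error of the log2 fold change.

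Gene types and positions came from GENCODE 29 on GRCh38, the assembly also called hg38, matched on the Ensembl ID without its version. Of the 60725 IDs, 57055 matched GENCODE 29 and 56558 matched a table of current and older gene symbols. Lists of genes were fixed before the data were examined: 24 lists with 495 symbols, of which 494 matched an ID. The unmatched symbol was H3C2, a histone gene. Some lists share genes and are not independent. XBP1 is on the oestrogen receptor and unfolded protein response lists. The amino acid synthesis and ATF4 list shares STC2 with the oestrogen receptor list and SESN2 with the p53 list. Symbols in the text are those of the files, except CCN1 and CCN2, which the files name CYR61 and CTGF. The filter on the mean keeps a gene that is low in wild type when it is high in knockout, so a list with many low genes can have a larger median after filtering, and its median with no filter is given beside it. Paralogs with near-identical sequence, such as histone, HLA, interferon lambda and ribosomal protein genes and their pseudogenes, can share reads, and how the authors assigned such reads is not given in the sources used here, so their values are less certain. Overlapping genes on opposite strands are uncertain for the same reason.

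Each list was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with a correlation estimated from the residuals is given beside it. In that form it also allows for the few samples behind the spread, which puts small p-values nearly out of reach. A call lost there need not be due to correlation between genes. The unfolded protein response list had an estimated correlation of 0.00983, near the preset, and its camera adjusted p still went from 2.35e-06 to 0.0583. Most other lists past the test had estimates well above the preset, the highest being 0.554 for the YAP/TAZ targets. NF-kB targets had 0.426, AP-1 genes 0.393 and oestrogen receptor targets 0.293, while histones had 0.0177 and antigen presentation -0.0576. For lists with a high estimate, the p-values at the preset correlation may be far too small. Fry from limma tested whether a list's genes moved, on balance, one way. Members were counted past the test over all genes tested and also adjusted over the list alone. Each chromosome was tested as a set in the same way, adjusted over 23 chromosomes.

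The genes named in the text were chosen by a rule fixed before the data were examined. They are LATS1 and LATS2; a panel of YAP1, WWTR1, CCN1, CCN2, ANKRD1, AMOTL2, ESR1, PGR, GREB1 and TFF1; and the 6 largest and 6 smallest log2 fold changes among protein-coding genes past the test. Genes of that last group needed a mean of at least 5 TPM and all 3 knockout samples on one side of all 3 wild-type samples, which chance alone gives for 10% of genes. From each list, the 2 members past the test with the smallest adjusted p were named. Further members of a list named as examples, and genes in the closing part on other observations, were chosen after their values were seen.

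The fit was tested on simulated data: 16198 genes drawn from a normal distribution around their real means with the moderated spread of the fit, and 50 genes with a mean of at least 5 TPM changed at each of 4 sizes. It recovered 4% of the genes changed by 0.5 on the log2 scale, 64% at 1, 78% at 2 and 94% at 4, with 9 false calls among the unchanged genes. The median estimated sizes were 0.50, 1.00, 1.99 and 3.99. In the real comparison many more genes changed, which lowers the adjusted p of each, so these shares describe a comparison with few changed genes. Noise was drawn independently for each gene and with the same spread in all 6 libraries. A deviation of 1 library shared across genes, as seen in knockout replicate 2, was not simulated.

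Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, the replicate number as a block, leaving out each sample in turn, an adjusted p under 0.01, an estimated correlation for lists and chromosomes, and the YAP/TAZ list without LATS2. Median-of-ratios scaling, upper-quartile scaling and a mean of at least 5 units had been planned for counts and were applied to TPM after seeing the data. Alternatives chosen after seeing the data were protein-coding genes only with each library rescaled to them, removal of each library's trend on transcript length and GC content, and 1 quality weight per library in limma. The trend was a local regression with a span of 0.3 on the longest transcript's length and GC content, which 94.5% of the tested genes had.

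To look along chromosomes, the median log2 fold change was taken in windows of 50 neighbouring tested protein-coding genes after subtracting the median of all 11427 such genes on chromosomes 1 to 22 and X. Windows were called shifted when their median lay beyond every window of 100 shuffled gene orders, and overlapping shifted windows were joined into regions. This was done after the chromosome medians had been seen. The search was repeated with windows of 25 on every other gene, and the genes between them were held out to test each region found. Scripts outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.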

Results

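The comparison asks how the MCF-7 transcriptome differs when the kinases LATS1 and LATS2 are knocked out. These are the core kinases of the Hippo pathway, which phosphorylate the transcriptional co-activators YAP1 and WWTR1 (also called TAZ). RNA from 3 wild-type samples and 3 LATS1/2 knockout samples was sequenced, and expression was given as TPM for 60725 genes. Between 31318 and 33052 genes had a value above 0 in each library, and read depth is unknown. CDKN2A and CDKN2B, which MCF-7 cells are known to lack, were listed at 0 in all 6 libraries. Across the 16198 genes tested, libraries of one group correlated at a Pearson r of 0.954 to 0.956 among wild type and at 0.953 between knockout replicates 1 and 3. Knockout replicate 2 stood apart, with r of 0.935 and 0.937 to the other knockout libraries.

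Knockout replicate 2 differed from the other knockout libraries by transcript length. Among protein-coding genes, split into 5 groups of similar size by transcript length, its median deviation from knockout replicates 1 and 3 was 0.10 on the log2 scale in the group with the shortest transcripts and -0.61 in the group with the longest. In the wild-type libraries the longest and the shortest group differed by between -0.03 and 0.01. Mitochondrial tRNA genes took 11.9% of the TPM of knockout replicate 2, against 10.4% and 10.2% in the other knockout libraries and 8.52% to 8.87% in wild type.

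**Figure D1:**
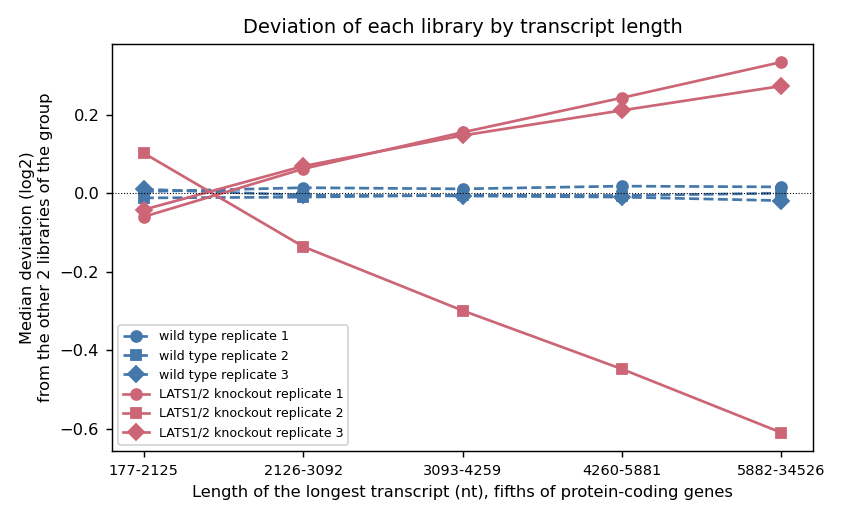
Median deviation of each library (log2) from the other libraries of its group, for 5 groups of the protein-coding genes by the length of their longest transcript in nucleotides. Knockout replicate 2 runs from 0.10 to -0.61, the wild-type libraries stay near 0, and knockout replicates 1 and 3 mirror replicate 2 because it is part of what they are compared with.

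LATS1 (ENSG00000131023.12, chromosome 6, 149658153 to 149718256 on GRCh38, minus strand) had 4.53, 4.67 and 4.53 TPM in wild-type replicates 1 to 3 and 3.28, 1.23 and 2.90 TPM in knockout replicates 1 to 3. The mean was 4.58 ± 0.0806 TPM (SD, n = 3) in wild type and 2.47 ± 1.09 TPM (SD, n = 3) in knockout. Its log2 fold change of -0.74 did not pass the limma test (adjusted p = 0.104), although all 3 knockout libraries lay below all 3 wild-type libraries. Without knockout replicate 2 it was -0.45 and passed (limma adjusted p = 0.00943). LATS2 (ENSG00000150457.8, chromosome 13, 20973032 to 21061547, minus strand), which is itself a target of YAP1, had 3.83, 3.42 and 3.21 TPM in wild type and 9.36, 4.35 and 9.70 TPM in knockout. Its log2 fold change of 0.91 did not pass either (limma adjusted p = 0.0802), and without knockout replicate 2 it was 1.23 (limma adjusted p = 0.001). No label names the edited exons, and an edit that shifts the reading frame need not lower the transcript, so these levels do not test the knockout.

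The knockout libraries had lower transcripts of the oestrogen receptor and of 21 of its 29 tested targets, and higher transcripts of 21 of 24 interferon response genes. The oestrogen receptor gene ESR1 was at 83.5 ± 6.22 TPM in wild type and at 3.33 ± 1.18 TPM in knockout (SD, n = 3 each), and the interferon-induced IFIT1 was at 0.350 ± 0.0166 and 63.4 ± 1.57 TPM. Of the 16198 genes tested, 3842 changed at an adjusted p under 0.05 in limma, 1673 higher and 2169 lower in knockout. At least a 2-fold change was reached by 722 of the higher and 436 of the lower genes. Protein-coding genes made up 11447 of the genes tested, with 1354 higher and 1921 lower. The median log2 fold change of all genes tested was -0.09 on the deposited scale. Without knockout replicates 1, 2 and 3, left out singly, it was -0.145, 0.006 and -0.135. It moved to 0.01 (0.005) with median-of-ratios scaling of all libraries, under which 2201 genes were higher and 1825 lower. That scaling changed mainly knockout replicate 2, whose factor was 0.843 against 1.02 to 1.04 in the other libraries. Higher genes were 43.5% of the calls on the deposited scale, 54.7% with that scaling and 48.2% without knockout replicate 2 on the deposited scale. The balance of directions thus depends on the scale and on that library. The total was 6775 without knockout replicate 2 (3263 higher and 3512 lower), and 3755 of these were called in the same direction with all libraries. It was 2129 (1063 and 1066), 2062 (1016 and 1046) and 2164 (1085 and 1079) without wild-type replicates 1, 2 and 3, and 2545 (1089 and 1456) without knockout replicate 3.

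**Figure D2:**
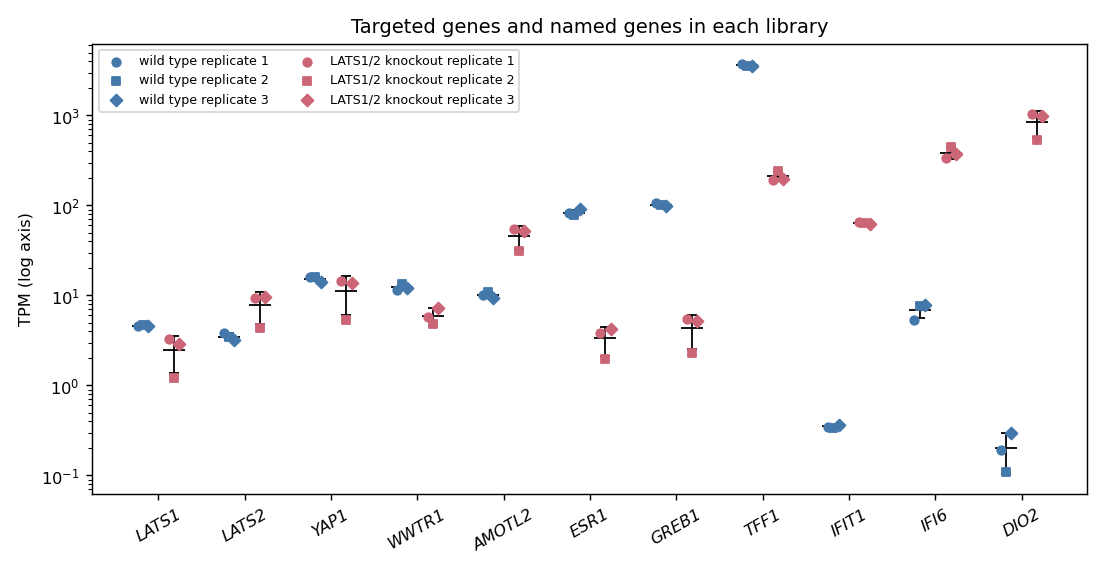
TPM (log axis) of the targeted genes and of 9 other named genes in each of the 6 libraries; bars are the mean and SD of 3 libraries, and symbols are replicates. ESR1, GREB1 and TFF1 lie lower in all 3 knockout libraries, and AMOTL2, IFIT1, IFI6 and DIO2 lie higher, while YAP1 did not pass the test (log2 fold change -0.54, and -0.11 without knockout replicate 2).

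The 6 largest rises were those of DIO2, IFI27, IFI6, IFIT1, ANXA3 and TGFB2. DIO2 (chromosome 14, 80197527 to 80387757), the enzyme that activates thyroid hormone, went from 0.200 ± 0.0960 to 852 ± 280 TPM (SD, n = 3), a log2 fold change of 9.41 ± 0.28 (SE, limma adjusted p = 6.33e-05). IFI27 (chromosome 14, 94104836 to 94116698) rose by 6.24 and IFI6 (chromosome 1, 27666061 to 27672218) by 5.62, both interferon-induced genes. ANXA3 (chromosome 4, 78551519 to 78610451), a calcium-dependent phospholipid-binding protein, went from 4.38 ± 0.761 to 199.7 ± 5.04 TPM. TGFB2 (chromosome 1, 218346235 to 218444619), a growth factor and a member of the YAP/TAZ target list, went from 0.0318 ± 0.0123 to 30.4 ± 6.42 TPM. The adjusted p of these genes in limma lay between 1.29e-05 and 0.000107.

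The 6 largest falls were those of EHF, GREB1, ESR1, KIAA1324, TFF1 and PKIB. EHF (chromosome 11, 34621093 to 34661057), an epithelial transcription factor of the ETS family, went from 31.1 ± 2.16 to 0.463 ± 0.0759 TPM (SD, n = 3), a log2 fold change of -4.45 ± 0.10 (SE, limma adjusted p = 4.23e-05). It lies in a part of chromosome 11 whose genes were lower as a group, described below. ESR1 (chromosome 6, 151656691 to 152129619) had a log2 fold change of -4.32 ± 0.23 (SE, limma adjusted p = 0.000293). GREB1 (chromosome 2, 11482341 to 11642788) and TFF1 (chromosome 21, 42362282 to 42366594) are classical oestrogen-induced genes. GREB1 went from 101.5 ± 4.86 to 4.33 ± 1.76 TPM, and TFF1 from 3590 ± 118 to 211 ± 26.1 TPM, which is 17.0-fold lower. KIAA1324 (chromosome 1, 109113679 to 109206781) had a log2 fold change of -4.21, and PKIB (chromosome 6, 122471917 to 122726373), an inhibitor of protein kinase A, of -4.07.

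Among the oestrogen receptor targets, 21 of 29 tested genes fell, 2 rose and 6 did not pass the test, with a median log2 fold change of -1.53. The list was lower than other genes in camera (adjusted p = 4.43e-10), and lost that call with an estimated correlation (adjusted p = 0.204). Adjusted over the list alone, 24 fell and 2 rose. TFF1 and XBP1 had the smallest adjusted p. XBP1, a transcription factor of the secretory pathway, went from 541 ± 7.68 to 83.8 ± 1.78 TPM. The protease CTSD went from 948 ± 54.4 to 142.5 ± 13.4 TPM and PDZK1 from 43.4 ± 1.43 to 4.98 ± 1.24 TPM. FHL2 and KCNK15 rose by 1.84 and 1.29, and CCND1 (-1.08) and MYC (-0.08) did not pass. CCND1 passed without knockout replicate 2 (-0.70, limma adjusted p = 0.00234), and KCNK15 fell under the filter when any one knockout library was left out. PGR, the progesterone receptor gene, was below the filter in both groups: 0.0480, 0.0410 and 0.0450 TPM in wild type, and listed at 0 in all 3 knockout libraries.

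YAP/TAZ targets were higher as a list, with a median log2 fold change of 0.89 over 15 tested genes of 22. Of these, 7 rose, 1 fell and 7 did not pass the test; adjusted over the list alone, 8 rose and 1 fell. Camera gave an adjusted p of 1.95e-05, and an adjusted p of 0.321 with an estimated correlation. With no filter on low values the median was 0.75 over 21 genes. Without LATS2 the list kept its 7 rises and 1 fall among 14 tested genes, and its median was 0.83. The count of rises was 13 without knockout replicate 2, with 1 fall. NT5E, which encodes the ectoenzyme CD73, had a log2 fold change of 3.85 ± 0.23 (SE, limma adjusted p = 0.000439) and TGFB2 one of 4.91. AMOTL2, a scaffold that binds YAP1, went from 10.2 ± 0.703 to 46.0 ± 12.9 TPM (log2 fold change 2.04, limma adjusted p = 0.00303). CCN1, named CYR61 in the files, went from 1.35 ± 0.0794 to 3.37 ± 0.606 TPM (limma adjusted p = 0.00909). FJX1 fell (log2 fold change -1.27) and lies in the lower part of chromosome 11. CCN2, named CTGF in the files, and ANKRD1 stayed under the filter: CTGF was at 0.0360 ± 0.0109 and 0.322 ± 0.0171 TPM, and ANKRD1 at 0.0206 ± 0.0128 and 0.0770 ± 0.0124 TPM (SD, n = 3 each). With no filter on low values CTGF passed as higher (limma adjusted p = 0.00916) and ANKRD1 did not pass (limma adjusted p = 0.0524). Both were far under 1 TPM in each group.

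Hippo pathway components went both ways, with 3 of 22 higher, 3 lower and 16 not past the test, the same counts as adjusted over the list alone, and no shift as a list (camera adjusted p = 0.891, and adjusted p = 0.957 with an estimated correlation). Without knockout replicate 2, 8 were higher and 4 lower, and the list's median moved from -0.16 to 0.09; it was -0.30 without knockout replicate 1 and -0.29 (-0.295) without knockout replicate 3. YAP1 had a log2 fold change of -0.54 ± 0.37 (SE) and did not pass (limma adjusted p = 0.358), and without knockout replicate 2 its fold change was -0.11 (adjusted p = 0.289). It had 14.6, 5.32 and 13.7 TPM in knockout replicates 1 to 3 and a mean of 15.4 ± 1.07 TPM in wild type. WWTR1 fell from 12.3 ± 0.865 to 5.97 ± 1.27 TPM (limma adjusted p = 0.0101) and TEAD2, a DNA-binding partner of YAP1, from 7.30 ± 2.26 to 2.51 ± 0.609 TPM (limma adjusted p = 0.0173). Neither passed in every setting: WWTR1 had an adjusted p of 0.0507 without wild-type replicate 2, and TEAD2 had 0.0508 without wild-type replicate 1 and 0.0567 without knockout replicate 3. With the replicate number as a block neither passed (0.0534 and 0.0787). VGLL3 and AMOTL1 rose with all libraries, by 1.75 and 1.51 on the log2 scale, but AMOTL1 did not pass when any library other than knockout replicate 2 was left out (limma adjusted p between 0.0714 and 0.0898). VGLL3 did not pass without any one wild-type library (0.105 to 0.107) and was under the filter without knockout replicate 1 or 3. In those 5 settings limma called no Hippo component higher, against 2 or 3 at an unadjusted p under 0.05, and called 1 or 2 lower.

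Interferon response genes were the list with the largest median, 2.78 on the log2 scale. Of 24 tested genes, 21 rose and 3 did not pass (MX1 1.02, MX2 0.52 and ISG20 0.30), and adjusted over the list alone 23 rose. MX1 and MX2 passed without knockout replicate 2 (limma adjusted p = 0.0128 and 0.0442). Camera gave an adjusted p of 4.42e-23, and an adjusted p of 0.0583 with an estimated correlation. IFIT1 and IRF9 had the smallest adjusted p. IRF9, a subunit of the transcription factor activated by type I and III interferons, went from 12.1 ± 0.631 to 154.9 ± 6.18 TPM, and ISG15, a ubiquitin-like protein, from 5.90 ± 0.550 to 185 ± 23.1 TPM. In the antigen presentation list 11 of 16 genes rose, 2 fell and 3 did not pass; 13 rose and 2 fell adjusted over the list alone. Its median was 1.05, with a camera adjusted p of 3.95e-08, and an adjusted p of 0.0583 with an estimated correlation. B2M, the light chain of class I molecules, went from 579 ± 8.27 to 1271 ± 42.0 TPM and PSMB9, an immunoproteasome subunit, from 1.72 ± 0.297 to 28.7 ± 2.42 TPM, while CALR and PDIA3, chaperones of the endoplasmic reticulum, fell. Neither fall passed with median-of-ratios scaling (limma adjusted p = 0.28 and 0.124), and CALR did not pass when any library other than knockout replicate 2 was left out (0.0721 to 0.0974). Of 14 markers of blood and endothelial cells, 2 were tested and neither passed (CD68 0.35, HBA1 -0.33; camera adjusted p = 0.891, and adjusted p = 0.94 with an estimated correlation), and PTPRC reached at most 0.0800 TPM in any library. Among the 12 under the filter, the means of CDH5 (0.0680 and 0.482 TPM), CD14 (0.239 and 0.664 TPM) and VWF (0.159 and 0.401 TPM) were higher in knockout than in wild type. Of the 12 fibroblast markers, COL1A1 was tested and did not pass (0.22; camera adjusted p = 0.594, and adjusted p = 0.682 with an estimated correlation).

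NF-kB targets, AP-1 genes and p53 targets were also higher as lists. Among the NF-kB targets, 6 of 20 were tested and 4 rose (5 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 0.000332, and adjusted p = 0.204 with an estimated correlation). With no filter on low values the NF-kB list had 18 tested genes and a median of 0.13, with 8 rises (camera adjusted p = 1.13e-06). IL6, a cytokine, was listed at 0 in all 3 wild-type libraries and had 3.86 ± 0.325 TPM in knockout, and NFKBIA, the inhibitor of NF-kB, rose by 1.08. Of 15 AP-1 and immediate early genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.64 (camera adjusted p = 0.000786, and adjusted p = 0.321 with an estimated correlation). The AP-1 median was 0.40 over 20 genes with no filter. DUSP1, a phosphatase of MAP kinases, rose by 1.80, and IER3 fell from 96.4 ± 6.33 to 20.7 ± 0.995 TPM. Of 21 p53 targets, 11 rose and none fell (13 and 0 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 1.78e-07, and adjusted p = 0.204 with an estimated correlation). They included BBC3 (1.47) and BAX (0.87), both promoters of apoptosis, GDF15 (2.06), a secreted stress factor, and CDKN1A (0.89), an inhibitor of the cell cycle. MDM2 had a log2 fold change of 0.21 and did not pass. In all, 17 p53 targets rose without knockout replicate 2, MDM2 among them (0.56, limma adjusted p = 0.00792). Only 8 rose when any other single library was left out, and 8 with the replicate number as a block.

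Luminal markers split, and basal markers were higher as a list. Of 20 luminal genes, 7 rose, 8 fell and 5 did not pass, the same counts as adjusted over the list alone. Its median was 0.05, its mean -0.42, camera gave an upward direction (adjusted p = 0.916, and adjusted p = 0.954 with an estimated correlation) and fry a downward one (adjusted p = 0.00161), so these summaries differ in sign. The median was -0.04 without knockout replicate 1 or 3 and 0.01 without knockout replicate 2. TFF3, a secreted trefoil peptide, went from 257 ± 8.33 to 20.9 ± 2.63 TPM, and SPDEF, an ETS family transcription factor, from 101.7 ± 1.14 to 25.6 ± 0.328 TPM. The keratins KRT8 (0.32) and KRT18 (0.52) rose, and GATA3 (0.04) did not pass. KRT8 did not pass with median-of-ratios scaling (limma adjusted p = 0.0653), and GATA3 passed without knockout replicate 2 (log2 fold change 0.19, adjusted p = 0.00951). The falls among luminal genes numbered 5 without any one wild-type library or knockout replicate 3. Of 12 basal and myoepithelial genes tested, 8 rose and 2 fell, as adjusted over the list alone, with a median of 0.92 (camera adjusted p = 0.00082, and adjusted p = 0.204 with an estimated correlation). That call was lost without knockout replicate 2 (adjusted p = 0.0558) and with a mean of at least 5 TPM, which left 3 genes (0.298), and with no filter the median was 0.52 over 21 genes. The median was 0.58 without knockout replicate 3. KRT17 rose from 0.111 ± 0.0314 to 5.05 ± 0.529 TPM, and CD44, a cell adhesion receptor, fell from 61.9 ± 0.601 to 29.5 ± 2.90 TPM. Of the 10 basal genes that passed, 4 lie in chromosome regions that shifted in the same direction (KRT15, KRT17, TP63 and CD44). TP63, a master regulator of basal cells, fell by 1.76.

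The mesenchymal list had 8 tested genes, of which 4 rose and 2 fell, as adjusted over the list alone, with a median of 0.92 (camera adjusted p = 0.0266, and adjusted p = 0.305 with an estimated correlation). With no filter the median was 0.05 over all 20 members, with 6 rises and 2 falls, and the call was lost (camera adjusted p = 0.0511). It was also lost without knockout replicate 2 (0.135), with the replicate number as a block (0.0515), with protein-coding genes only (0.105), with a mean of at least 5 TPM (0.848) and with the length and GC trend removed (0.0648). SNAI2, a transcriptional repressor of epithelial genes, went from 0.0605 ± 0.0254 to 8.65 ± 0.149 TPM and COL5A1, a fibrillar collagen, from 0.205 ± 0.0514 to 4.49 ± 0.814 TPM, while THBS1 fell by 2.58. Of 23 actin cytoskeleton and focal adhesion genes, 9 rose and none fell; adjusted over the list alone, 9 rose and 1 fell. The median was 0.32 (camera adjusted p = 0.000118, and adjusted p = 0.321 with an estimated correlation). Without knockout replicate 2, 17 rose and 2 fell and the median was 0.67; it was 0.12 without knockout replicate 1 and 0.17 without knockout replicate 3. FLNA and FLNB, which crosslink actin, rose by 1.66 and 0.85, and the actin-binding CALD1 by 2.23.

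Lists of the cell cycle and of biosynthesis were lower. Of 20 mitosis genes, 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.48 (-0.485; camera adjusted p = 0.000118, and adjusted p = 0.204 with an estimated correlation). BIRC5 fell by 0.61 and CDC20, an activator of the anaphase-promoting complex, by 0.75; TOP2A rose by 0.44 and lies in the higher region of chromosome 17. TOP2A did not pass without any one wild-type library or knockout replicate 1 (limma adjusted p between 0.0728 and 0.0977), nor with median-of-ratios scaling (0.0565). The falls among mitosis genes numbered 5 without any one wild-type library. Of 22 DNA replication genes, 9 fell and 2 rose (13 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.00141, and adjusted p = 0.204 with an estimated correlation). ORC1, of the origin recognition complex, fell by 0.83 and GINS2, of the replicative helicase, by 0.80, while CCNE1 rose by 0.66. Falls were called for 15 mitosis genes and 15 replication genes without knockout replicate 2. The falls among replication genes numbered 5 without wild-type replicate 2 or 3, and 1 gene rose without any one library other than knockout replicate 2. In the unfolded protein response list, 13 of 17 genes fell and none rose, as adjusted over the list alone, with a median of -0.56 (camera adjusted p = 2.35e-06, and adjusted p = 0.0583 with an estimated correlation). The falls in this list numbered 6 and 8 without wild-type replicates 2 and 3, and 7 with median-of-ratios scaling. HSPA5, the main chaperone of the endoplasmic reticulum, went from 130.6 ± 1.84 to 88.1 ± 2.45 TPM. XBP1, which is also on the oestrogen receptor list, was among the falls (log2 fold change -2.675). Of 18 amino acid synthesis and ATF4 target genes, 14 fell and 2 rose, as adjusted over the list alone, with a median of -0.80 (camera adjusted p = 2.64e-05, and adjusted p = 0.204 with an estimated correlation). SLC3A2 and SLC7A5, the subunits of an amino acid transporter, had log2 fold changes of -2.03 and -2.79 (-2.788), and TRIB3 went from 30.35 ± 0.0534 to 14.7 ± 0.436 TPM. SLC3A2 lies in the lower part of chromosome 11, and 1 gene of the list rose without any one wild-type library. In cholesterol and fatty acid synthesis, 12 of 25 genes fell and none rose (13 and 0 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 0.000159, and adjusted p = 0.321 with an estimated correlation). The list had 16 falls and 3 rises without knockout replicate 2, and 7 falls without wild-type replicate 1 or 3. SCD, a fatty acid desaturase, went from 256 ± 3.09 to 77.8 ± 18.0 TPM, and FDFT1, which makes squalene, from 136 ± 3.71 to 86.2 ± 3.96 TPM.

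Replication-dependent histone genes were higher as a list: of 9 tested, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.000597, and adjusted p = 0.147 with an estimated correlation). With no filter the histone median was 0.34 (0.335) over 18 genes. HIST1H2AC and HIST1H4H rose by 0.96 and 1.20. The fall was not called without wild-type replicate 3, nor with median-of-ratios or upper-quartile scaling, under each of which 7 rose. In fry, all 16 lists that passed camera moved in the direction camera gave, with adjusted p between 4.74e-06 and 0.00873. Fry does not compare a list with other genes. The remaining lists did not pass camera. Of 21 hypoxia and glycolysis genes, 8 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.133, and adjusted p = 0.565 with an estimated correlation); ALDOA, a glycolytic enzyme, fell by 0.48 but did not pass after median-of-ratios scaling (limma adjusted p = 0.0543), and ADM, a secreted peptide, rose by 1.62. Of the hypoxia list, 6 rose and 10 fell without knockout replicate 2, and 1 rose without wild-type replicate 1 or 2. Of 22 nuclear genes of oxidative phosphorylation, 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.594, and adjusted p = 0.94 with an estimated correlation), among them SDHA (0.54) and ATP5G3 (-0.71). Without knockout replicate 2, 4 rose and 12 fell and the list was lower (camera adjusted p = 0.0123), while without the wild-type replicates or knockout replicate 3, left out singly, 1 or 2 rose. Of 13 mitochondrially encoded genes, MT-CO3 rose by 0.37 and the others did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.0674, and adjusted p = 0.528 with an estimated correlation); without knockout replicate 2, 9 rose and 1 fell (camera adjusted p = 0.00236). That list was also higher with median-of-ratios scaling (4 rises, camera adjusted p = 0.0401), upper-quartile scaling (0.0421) and a mean of at least 5 TPM (0.0331). Of 26 cytosolic ribosomal protein genes, RPL19 and RPL27 rose, RPL32 fell and 23 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.406, and adjusted p = 0.94 with an estimated correlation). Without knockout replicate 2, 5 rose and 12 fell, and without knockout replicate 1 the list was higher (camera adjusted p = 0.024). RPL32 did not pass when any one of 5 libraries was left out (limma adjusted p between 0.0539 and 0.0696), nor with median-of-ratios scaling (0.113). RPL19 reached 0.05 without wild-type replicate 3, and RPL27 did not pass without any one wild-type library or knockout replicate 3 (0.0588 to 0.105), nor with median-of-ratios scaling (0.0709). RPL19 and RPL27 lie in the higher region of chromosome 17 and RPL32 in a lower region of chromosome 3.

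**Figure D3:**
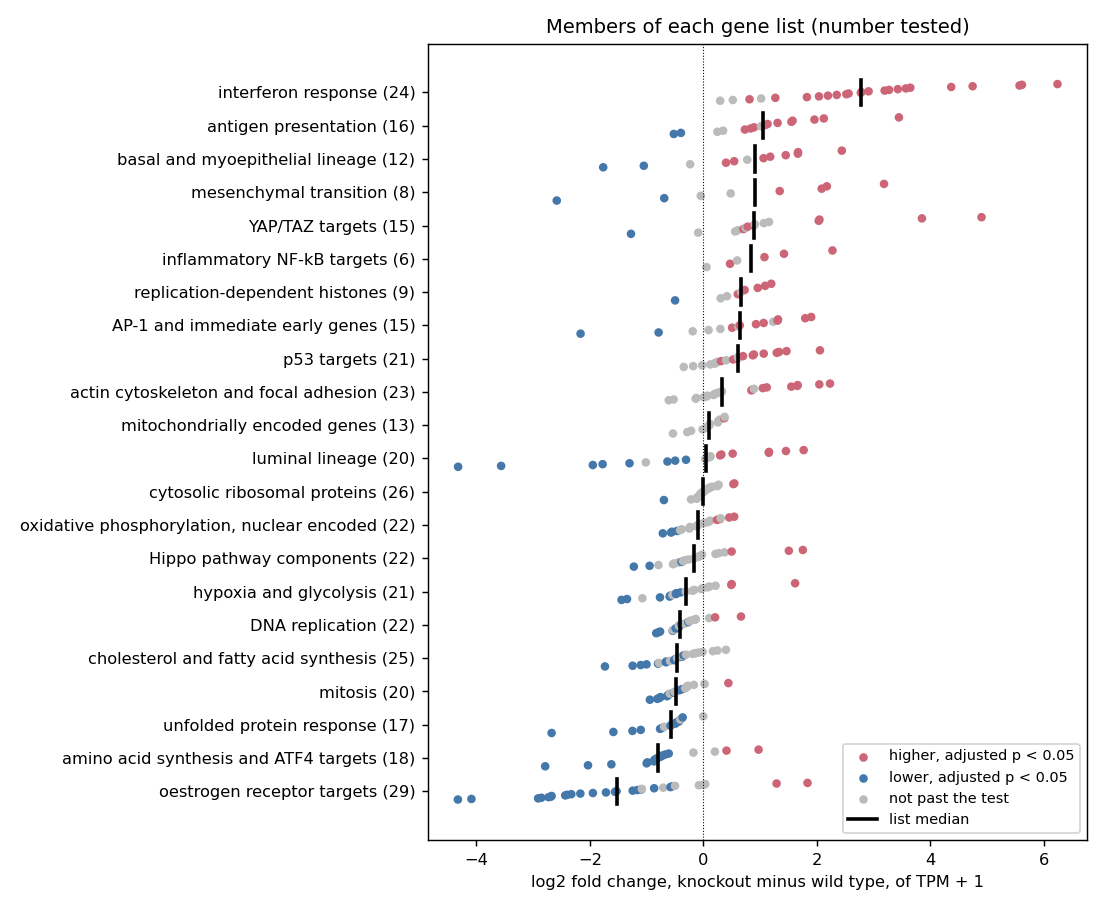
Log2 fold change (knockout minus wild type, TPM + 1) of each tested member of the 22 lists with at least 6 tested genes; points are genes, coloured by whether they passed the limma test, and black bars are list medians. Medians run from -1.53 for the oestrogen receptor targets to 2.78 for the interferon response genes.

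Genes on 4 of the 23 chromosomes were shifted as sets in camera. Chromosomes 3 and 11 had median log2 fold changes of -0.24 and -0.25 over 844 and 820 genes (adjusted p = 0.0182 and 0.0203), and chromosomes 13 and 17 had 0.08 and 0.09 over 255 and 998 genes (adjusted p = 0.0182 for each). No chromosome passed with an estimated correlation (adjusted p = 0.994 for each) or without the filter on low values, and 3 passed without knockout replicate 1. Within chromosomes, windows of 50 neighbouring protein-coding genes formed 9 regions beyond the range of -0.35 to 0.36 found in 100 shuffled gene orders. This was computed after the chromosome medians were seen. On chromosome 3 genes were lower in 3 regions, 3126916 to 37183689, 69054730 to 123585185 and 153162270 to 198043720, with lowest window medians of -0.64, -0.53 and -0.61. On chromosome 11 they were lower at 9778667 to 46846308 (-0.49) and 57299638 to 66646469 (-0.60), and on chromosome 16 at 67227103 to 75110994 (-0.37). They were higher on chromosome 17 at 28854938 to 50485975 (0.59), on chromosome 13 at 60396457 to 114337626 (0.42) and on chromosome 1 at 147175351 to 151249536 (0.37). The shift had the same sign in each knockout library in all 9 regions. The regions were found from these same libraries together, against the same wild-type mean, so the shared sign is not an independent check. These regions held 1031 of the 11427 genes. Within them 118 higher and 308 lower genes had the direction of their region, among 3273 protein-coding genes past the test on chromosomes 1 to 22 and X. These counts rest on the fold changes that defined the regions.

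**Figure D4:**
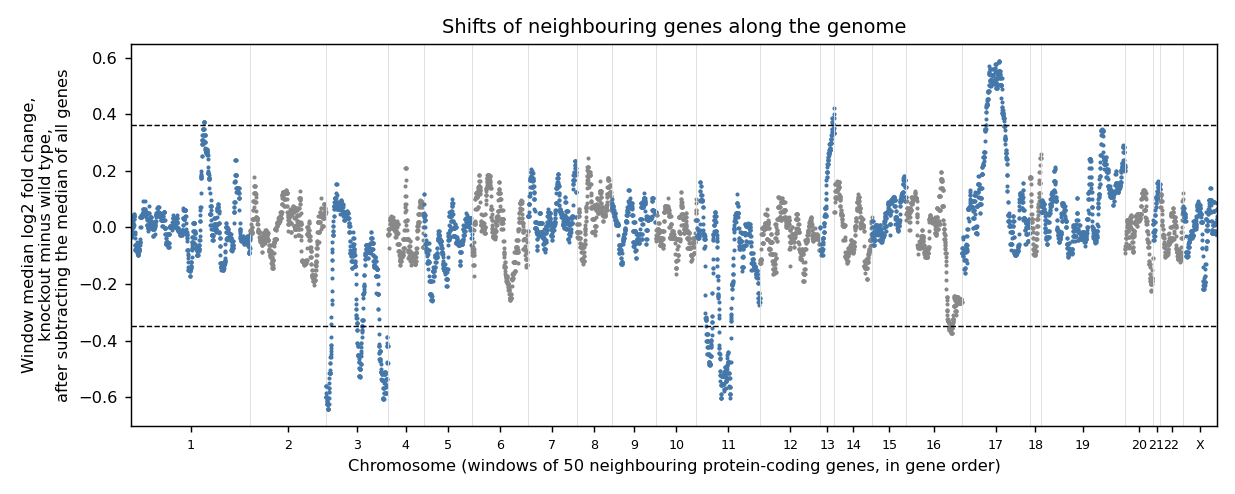
Median log2 fold change (knockout minus wild type, after subtracting the median of all genes) of windows of 50 neighbouring protein-coding genes, in gene order along chromosomes 1 to 22 and X. Dashed lines mark the most extreme windows of 100 shuffled gene orders, -0.35 and 0.36; windows on chromosomes 3, 11 and 16 lie below and on chromosomes 1, 13 and 17 above.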

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

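Median-of-ratios and upper-quartile scaling and the mean of at least 5 TPM had been planned for counts and were applied to TPM after seeing the data; protein-coding genes only, removal of the length and GC trend, and library weights were chosen then. No LATS or named gene changed sign. The medians of 6 lists did: Hippo components (-0.16, and 0.09 without knockout replicate 2), ribosomal proteins (-0.00, and 0.11 with median-of-ratios scaling), oxidative phosphorylation (-0.09, and 0.02 with that scaling), luminal (0.05, and -0.04 without knockout replicate 1), mesenchymal (0.92, and -0.05 with a mean of at least 5 TPM) and blood and endothelial markers (0.01, and -0.10 without wild-type replicate 1). The count of 3842 changed genes (1673 higher, 2169 lower) moved to 8626 (4181 and 4445) with library quality weights, in which knockout replicate 2 had a weight of 0.073, and to 1815 (890 and 925) at an adjusted p under 0.01. With a mean of at least 5 TPM, 1074 genes were higher and 1922 lower, so 35.8% of the calls were higher against 43.5%; the cause of this shift was not tested. Leaving out 1 library gave between 2062 and 6775 changed genes, 1016 to 3263 higher and 1046 to 3512 lower. With the replicate number as a block, 2016 genes passed (972 higher, 1044 lower). Same-numbered samples showed little shared deviation (r = 0.024, 0.011 and -0.007 across genes). Wild-type replicates 1 and 2 correlated best with the knockout replicate of their own number, and wild-type replicate 3 with knockout replicate 2 (r = 0.015). The length trend of knockout replicate 2 was left in these deviations. A pairing could therefore be missed, and the check does not decide the question.

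LATS1 passed the test without knockout replicate 2 (log2 fold change -0.45), with the length and GC trend removed (-0.60) and with library quality weights (-0.51); leaving out 1 library gave -0.92 (-0.922) to -0.45. LATS2 ranged from 0.73 (0.733) to 1.23 (1.233) when 1 library was left out. It passed without knockout replicate 2 (1.23) and with median-of-ratios scaling (1.00, 0.997), upper-quartile scaling (1.00, 0.998), protein-coding genes only (1.01), the trend removed (0.97) and library quality weights (1.24). The cause of these changes was not tested beyond the length trend of knockout replicate 2. Of the 16 lists past the test, 0 passed with an estimated correlation, and of the 4 chromosomes 0 did. That setting allows for the few samples as well as for correlation, so these losses do not show that correlated genes gave the calls. Nor do they exclude it for the lists with a high estimated correlation. Without the filter on low values, 0 chromosomes passed. Over named genes, 786 combinations of gene and setting kept the main result, passing or not, and 16 lost a call, among ALDOA, RPL19, RPL32, TEAD2 and WWTR1. Over lists, 352 combinations of list and setting kept the main result, passing or not, 24 lost a call and 6 gained one. Camera was run without the library quality weights, so for lists and chromosomes that setting only repeats the main test. The count-based tests and normalizations planned for count files were not run because the files hold no counts, and scaling by library size alone is the deposited scale.

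Of the 10 splits of the 6 samples into 3 and 3, 1 (the real one) gave as many as 3842 changed genes, and the highest of the others gave 3; with 10 splits the share cannot fall under 0.1, so this count is too small to judge chance.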

Other observations

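Genes in this paragraph were chosen after their values were seen. The transcripts of interferons themselves were low but higher in every knockout library: IFNB1 had a mean of 0.00900 TPM in wild type and 0.232 TPM in knockout, IFNL1 had 0.0340 and 0.832 TPM, and IFNL3 had 0.0370 and 0.579 TPM. IFNL2 was listed at 0 in all 3 wild-type libraries and had 0.595 TPM in knockout. The uroplakin genes UPK2, UPK3A and UPK3B rose by 4.11, 2.92 and 4.01 on the log2 scale, and the uroplakin family was not tested as a list. VGLL1, a co-factor of TEAD proteins, went from 0.102 to 29.2 TPM (log2 fold change 4.78). The chemokine CCL5, which lies in the higher region of chromosome 17, rose by 3.60 and the Wnt inhibitor DKK1 by 4.30.

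Genes next to ESR1 and EHF were looked at after those falls were seen. All 5 tested protein-coding genes within 500 kb of ESR1, itself included, fell: ARMT1 from 85.8 ± 1.19 to 14.6 ± 2.14 TPM (SD, n = 3), RMND1 from 41.7 ± 1.19 to 8.94 ± 1.02 TPM, CCDC170 from 3.76 ± 1.02 to 0.3615 ± 0.148 TPM and ZBTB2 from 8.80 ± 0.0623 to 4.14 ± 0.618 TPM. Their log2 fold changes were -2.49, -2.11, -1.79 and -0.94, with adjusted p between 0.000194 and 0.00426 in limma. Beside EHF, the related ELF5 went from 34.4 ± 0.211 to 1.94 ± 0.636 TPM, and PDHX, APIP, CD44, NAT10 and CAT had log2 fold changes of -1.32, -1.11 (-1.115), -1.05, -0.60 and -0.48 (-0.485), while ABTB2 (-0.27) did not pass (limma adjusted p = 0.289). They lie in a region of chromosome 11 that was lower as a whole. Of the cytosolic ribosomal protein genes, all 3 that passed the test lie in regions that shifted in their direction.

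In the 3 patterns that follow, the tests for GC content and length in the regions and for interferon genes inside regions were chosen before their results were seen, and the other tests after. Knockout replicate 2 stood apart from its group, and its deviation fell with transcript length (Spearman rho = -0.593 across protein-coding genes, which are not independent replicates), against -0.09 to 0.547 in the other 5 libraries, where knockout replicates 1 and 3 are set against it. One scale factor, as when a few abundant genes take a larger share, would move all lengths alike, but the longest of the 5 length groups lay 0.71 (-0.712) below the shortest. Wild-type RNA mixed in would place it between its sources, yet 73.2% of the genes in the longest of 5 length groups were lower there than in every other library, which argues against it as the source of the length pattern. A small share of wild-type RNA stays open: with the length and GC trend removed, genes 2-fold lower in knockout replicate 1 were 0.12 higher in replicate 2 than in 3, those chosen by replicate 3 were 0.09 higher than in 1, and genes 2-fold higher were 0.00 apart. A loss of long transcripts in that RNA or library may account for the pattern, and no biological explanation was tested.

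Contiguous regions of chromosomes 1, 3, 11, 13, 16 and 17 shifted together. Regions were sought anew with every other gene, and the genes held out between them lay beyond 100 shuffled orders in the same direction in 11 of 12 regions, all on chromosomes 3, 11 and 17. After removal of the length and GC trend, 8 of the 9 still held a window beyond the shuffled orders, which argues against GC content or transcript length as the whole cause. The exception was the region on chromosome 1, where the peak went from 0.37 to 0.35. Regional copy number differing between the wild-type and knockout cells may account for the shifts on chromosomes 3, 11 and 17, but DNA was not measured, and regulation over whole domains would give the same.

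Interferon response genes were higher in knockout. Blood or immune cells in the cultures would bring their abundant transcripts, but 0 of 14 markers of such cells reached 1 TPM and lay above wild type in every knockout library. A regional copy number gain of the members themselves was argued against, since 0 of the 21 called members, on 10 chromosomes, lay in regions that shifted upwards. Those regions held 55, 70 and 223 of the 11427 genes, so few members would lie there by chance. Copy number changes smaller than a window, and effects through genes elsewhere, were not tested. The 4 interferon transcripts summed to 2.24 (2.238) TPM in knockout and 0.0800 TPM in wild type, so an interferon response within these cultures may be one source. Whether it followed from the genotype or from an exposure of the knockout cultures other than the genotype cannot be told apart with 1 knockout group.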
